A study of Mus musculus with 6 samples.

How the data were processed

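Microglia from the optic nerves of 3-month-old C57BL/6 mice were enriched on a Percoll gradient and sorted by flow cytometry, per the labels' protocols. Total RNA was extracted with TRIzol, amplified to cDNA with the Ovation RNA-Seq method for small inputs, sheared, and sequenced as paired ends on an Illumina HiSeq. The submitters' processing notes name CASAVA 1.8.2, TopHat2 2.0.4, Bowtie2 2.0.0 and Cufflinks 2.0.2 and the mouse build mm9, without roles or settings. The deposited table holds FPKM values by the authors for each Ensembl gene in each of the 6 libraries, with a symbol and a position. No counts were used here, so tests for counts do not apply, and the strand setting of the counting is not given in the sources used here. An FPKM is a level relative to all other fragments of its library. Coordinates are those of the table in mm9, given from 1; the annotation supplied with the data is of another build and was not used for positions. All 6 value columns were matched to libraries by name, and no other sample columns are in the table.

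The table lists 37447 genes, of which 426 have no value in at least 1 library and were left out of every fit, and 7042 are at 0 in all libraries. Of 37 mitochondrial genes 32 are at 0 in all libraries, although cells transcribe them abundantly, so a value of 0 may be a failed estimate: genes at 0 are said to be listed at 0 and are given per library. Depth relative to FMC 2 was estimated from low values (0.02 to 0.5 FPKM), where the ratio of a gene's values in 2 libraries piles up at ratios of small whole numbers times the ratio of depths. A joint estimate over 15 pairs of libraries lay within 0.1 (log2) of the estimate from each pair alone in 11 pairs; the other 4 all hold FM 2 and lie about 1 doubling away. Precision is set mainly by the spread between libraries, with a median residual SD of 0.84 (log2), and not by a known count.

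Values were tested as log2(FPKM + 1) over the 18208 genes with at least 1 FPKM in at least 2 of the 6 libraries. A fold on that scale understates the change of low genes. Fits used limma 3.58.1 in R 4.3.3 with an intensity trend, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The genotype comparison had no covariate; the sex comparison kept genotype; another fit added the interaction. Ccl5 also had an exact permutation test over the 15 splits into 4 and 2 libraries, which cannot give a p under 0.0667. The lists were tested with camera at its preset correlation of 0.01, adjusted over the 31 lists, all with at least 3 measured members. In the fits that leave out an FM library, the lone FM library is assumed to vary like the FMC group.

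The 31 lists, the tests, the groups and the alternatives were fixed before the data were examined. The lists cover microglial states (homeostatic, disease-associated), chemokines and their receptors, interferon-stimulated genes, MHC class I and class II presentation, pro-inflammatory cytokines, alternative activation, growth factors and matrix remodelling, Ras-MAPK feedback, the cell cycle, immediate early and dissociation stress, phagocytosis and complement, ribosomal proteins and oxidative phosphorylation. They also cover markers of oligodendrocytes and their precursors, astrocytes, neurons, photoreceptors, endothelium, pericytes and fibroblasts, T cells, NK and cytotoxic cells, B cells, monocytes, border-associated macrophages, neutrophils, dendritic cells and erythroid cells. Where several rows share a symbol, the row with the highest mean was used.

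Genes named in the text follow a rule. Nf1, Gfap and Ccl5 are always given, and Xist, Ddx3y, Eif2s3y, Kdm5d and Uty as a check of the sex labels. In each direction up to 12 genes are named: those past the threshold with groups that do not overlap, by size of the difference, then those with the smallest p that do not overlap and have a mean of at least 5 FPKM. Small RNAs with the symbol patterns fixed in advance, predicted genes and bare identifiers are not named by the rule, and clone-based identifiers and upper-case small nucleolar RNA symbols were read as falling under it. For lists past the threshold the 3 members with the smallest p are named, and for the others the first, a reduction from up to 3 that was made after the lists were tested. The rule also allows up to 5 genes per direction for sex and up to 3 for the interaction, and none passed.

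The alternatives were a pseudocount of 0.1, no filter, a mean of at least 5 FPKM, median ratio scaling, quantile normalization, no intensity trend, array weights, omission of small and unnamed RNAs, sex as a covariate, blocks by replicate number or by title dates 1 day apart (the labels do not say what the dates record), omission of each library, and an estimated correlation for the lists. The fry test of the lists was added after the data were seen. The scripts were tested on data simulated from the means and spreads of the 18208 genes, with 200 genes changed in each of 10 runs: 0% of 2-fold, 4.20% of 4-fold, 70.4% of 16-fold and 96.6% of 64-fold changes were recovered, with 6.60 false calls per run on average. The changed genes were drawn from those with higher means, and simulated values do not pile up at 0, so recovery of low genes was not measured. A list shifted by 0.7 (log2) was called in 10 of 10 runs. In runs with independent genes and no change 0 lists were called, and 3 of 10 such runs called genes. Such runs do not show how often lists are called falsely when their members vary together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.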

Results

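RNA was sequenced from microglia, the resident macrophages of nervous tissue, sorted from the optic nerves of 3-month-old C57BL/6 mice. The 6 libraries fall into 2 genotypes. In the control group, called FM, mice carried 1 floxed and 1 mutant allele of Nf1, the gene mutated in neurofibromatosis type 1 (2 libraries, FM 1 labelled male and FM 2 labelled female). The group called FMC carried the same alleles and Cre recombinase under the GFAP promoter, which is active in astroglial cells (4 libraries, FMC 1 and FMC 4 labelled female, FMC 2 and FMC 3 male). The labels call the libraries biological replicates. The deposited table gives FPKM, fragments scaled by transcript length and by the mapped total of the library, for 37447 genes. Between 13390 (FMC 3) and 15562 (FM 2) genes reached 1 FPKM in a library, and the FPKM of a library summed to between 420285 (FM 1) and 674799 (FMC 1). Read totals per library were not used here. From the steps of low FPKM values the depth relative to FMC 2 was estimated as 1.17 for FM 1, 1.67 for FM 2, 1.38 for FMC 1, 1.99 for FMC 3 and 2.13 for FMC 4. For FM 2 the median over its own pairs of libraries gave 3.34 instead. Libraries of 1 genotype resembled each other no more than libraries of different genotypes. Across the 18208 genes tested, which are not independent replicates, Pearson's r was 0.686 for the FM pair, 0.668 to 0.757 within FMC and 0.667 to 0.758 between the groups.

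The comparison of FMC with FM asks which genes differ in optic nerve microglia when the mice also carry the Cre transgene, in a study of optic glioma whose title names the chemokine Ccl5. Ccl5 stood at 2.35 and 3.05 FPKM in the 2 FM libraries and at 34.0, 38.6, 113 and 471 FPKM in the 4 FMC libraries. Its means were 2.70 ± 0.49 FPKM (SD, n = 2) in FM and 164 ± 208 FPKM (SD, n = 4) in FMC. Ccl5, which encodes a chemokine that attracts T cells and monocytes (ENSMUSG00000035042), lies on chromosome 11 from 83339280 to 83344020 in the mm9 build. The difference was 4.66 ± 0.98 (SE) on the log2(FPKM + 1) scale, a fold of 25.2. It did not pass the test across all genes (limma, adjusted p = 0.365). In an exact two-sided permutation test the real split gave p = 0.0667, the smallest that 15 splits allow. Between libraries whose titles carry dates 1 day apart, Ccl5 was higher in FMC 2 than in FM 1 by 3.39 and higher in FMC 3 than in FM 2 by 3.29 (log2). FMC 3 is labelled male and FM 2 female, so each difference between them mixes sex with genotype. Over the list of chemokines fixed before the data were examined, Ccl5, Cxcl9 and Cxcl13 passed with p adjusted over the list alone.

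Nf1 itself was 44.7 ± 7.6 FPKM (SD, n = 2) in FM and 75.0 ± 42.5 FPKM (SD, n = 4) in FMC, a log2 difference of 0.61 ± 0.53 (SE, limma adjusted p = 0.993). By library it was 48.0, 58.1, 55.6 and 138 FPKM in FMC 1 to FMC 4, so the FMC mean rests largely on FMC 4. With 1 library left out the log2 difference ran from 0.27 to 0.78. A level in sorted microglia does not check a deletion driven in GFAP-expressing cells. Gfap, which encodes the astrocyte intermediate filament, was between 0.183 and 0.309 FPKM in 5 libraries and 3.06 FPKM in FM 2. It lay under the filter of the limma fit, and an exact permutation test of its log2 difference of -0.80 gave p = 0.333.

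Across all genes limma called 0 genes higher and 5 genes lower in FMC at an adjusted p under 0.05. The 5 genes that fell are small RNAs or unnamed gene models, outside the rule for named genes and named here after their values were seen. SNORA40, a small nucleolar RNA gene on chromosome 7 from 29136527 to 29136651, was at 309 and 153 FPKM in FM 1 and FM 2 (adjusted p = 0.0239). AC122806.1 on chromosome 8 (15418536 to 15418645) was at 100.4 and 158 FPKM in FM 1 and FM 2. AC102205.1 on chromosome 7 (65664241 to 65664350) was at 99.9 and 158 FPKM there, AC122327.1 on chromosome 12 (22801051 to 22801160) at 99.2 and 79.9 FPKM, and SNORA19 on chromosome 19 (60851424 to 60851542) at 65.5 and 300.4 FPKM. All 5 are listed at 0 in all 4 FMC libraries, so no fold is given. All 5 are short by their coordinates, so a high FPKM can rest on few fragments, and no counts were used here. AC122806.1 and AC102205.1 have nearly equal values in each FM library, so they may share reads and not be separate calls. At an unadjusted p under 0.05 there were 973 genes, 208 higher and 765 lower, where 910 of 18208 are expected by chance. More calls lower than higher is not particular to genotype. At the adjusted threshold, FMC 1 and FMC 2 against the rest gave 0 genes higher and 7 lower in the other 4. FMC 1 and FMC 3 against the rest gave 6 and 15. The splits of FM 2 and FMC 4 (20 and 9) and of FM 1 and FMC 4 (1 and 0) went the other way. All FMC libraries lay above both FM libraries in 790 genes (4.34%) and below both in 1496 (8.22%), where chance gives 6.67% in each direction if no values tie. Values of 0 tie, and a gene at 0 in more libraries than FM has cannot lie above. Chance therefore gives less than 6.67% for that direction, here and where 6.67% is given for the lists. The median log2 difference of all genes was -0.12, and it was -0.09 after median ratio scaling and 0.04 after quantile normalization. The count of 5 became 0 with sex as a covariate and without either FMC 2 or FMC 3. Without FM 1 or FM 2 the 5 genes reached 1 FPKM in only 1 library and fell under the filter. Those fits could therefore not test them. Without FMC 1 there were 0 genes higher and 4 lower, and without FMC 4 there were 4 higher and 4 lower. In simulated data with the spreads of these 18208 genes, the same fit recovered 0% of changes of 2-fold, 4.20% of 4-fold, 70.4% of 16-fold and 96.6% of 64-fold. These shares hold for the genes with higher means that were changed, and not for low genes.

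No gene with a name outside those classes passed the test, so the following are values of the 12 genes in each direction with the smallest p among genes whose groups did not overlap and whose mean was at least 5 FPKM. Slamf7, a receptor of activated immune cells, was 2.10 ± 1.16 FPKM (SD, n = 2) in FM and 29.8 ± 15.8 FPKM (SD, n = 4) in FMC (log2 difference 3.24 ± 0.64 SE, adjusted p = 0.303). Cxcl9, a chemokine induced by interferon gamma, was 4.20 ± 0.90 FPKM in FM and 46.2 ± 32.1 FPKM in FMC, and Cxcl13, which attracts B cells, was 43.3 ± 2.7 and 241 ± 148 FPKM. Oas2, an interferon-induced sensor of double-stranded RNA, was 11.1 ± 2.8 and 50.5 ± 14.1 FPKM. Gpnmb, a transmembrane glycoprotein of activated microglia, was 0.259 ± 0.277 and 9.01 ± 3.33 FPKM. The mitochondrial cochaperone gene Hscb was 8.36 ± 4.86 and 50.8 ± 17.3 FPKM, the actin regulator Lrrc16a 13.3 ± 10.6 and 79.7 ± 34.2 FPKM, and the deubiquitinase gene Usp45 3.26 ± 1.03 and 19.0 ± 3.1 FPKM. The immunoglobulin kappa variable segment Igkv17-127 was at 2.51 and 1.16 FPKM in FM and between 66.9 and 428 FPKM in FMC (log2 difference 6.11 ± 0.80 SE, adjusted p = 0.0771). Without FMC 4 it passed (adjusted p = 0.0326; 0.0326 to 0.925 over all alternatives). A second segment, Igkv8-21, was listed at 0 in FM 1 and at 2.65 FPKM in FM 2, against 99.7, 13.2, 342 and 309 FPKM in FMC 1 to FMC 4. The small nucleolar RNA snoU6-77 was at 24.1 and 0 FPKM in FM and 228, 121, 268 and 73.8 FPKM in FMC. Reads of near-identical immunoglobulin segments can be split between them, so these values are uncertain. Adjusted p ran from 0.0771 to 0.487 over these 12 genes, with Ccl5 among them.

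**Figure D1:**
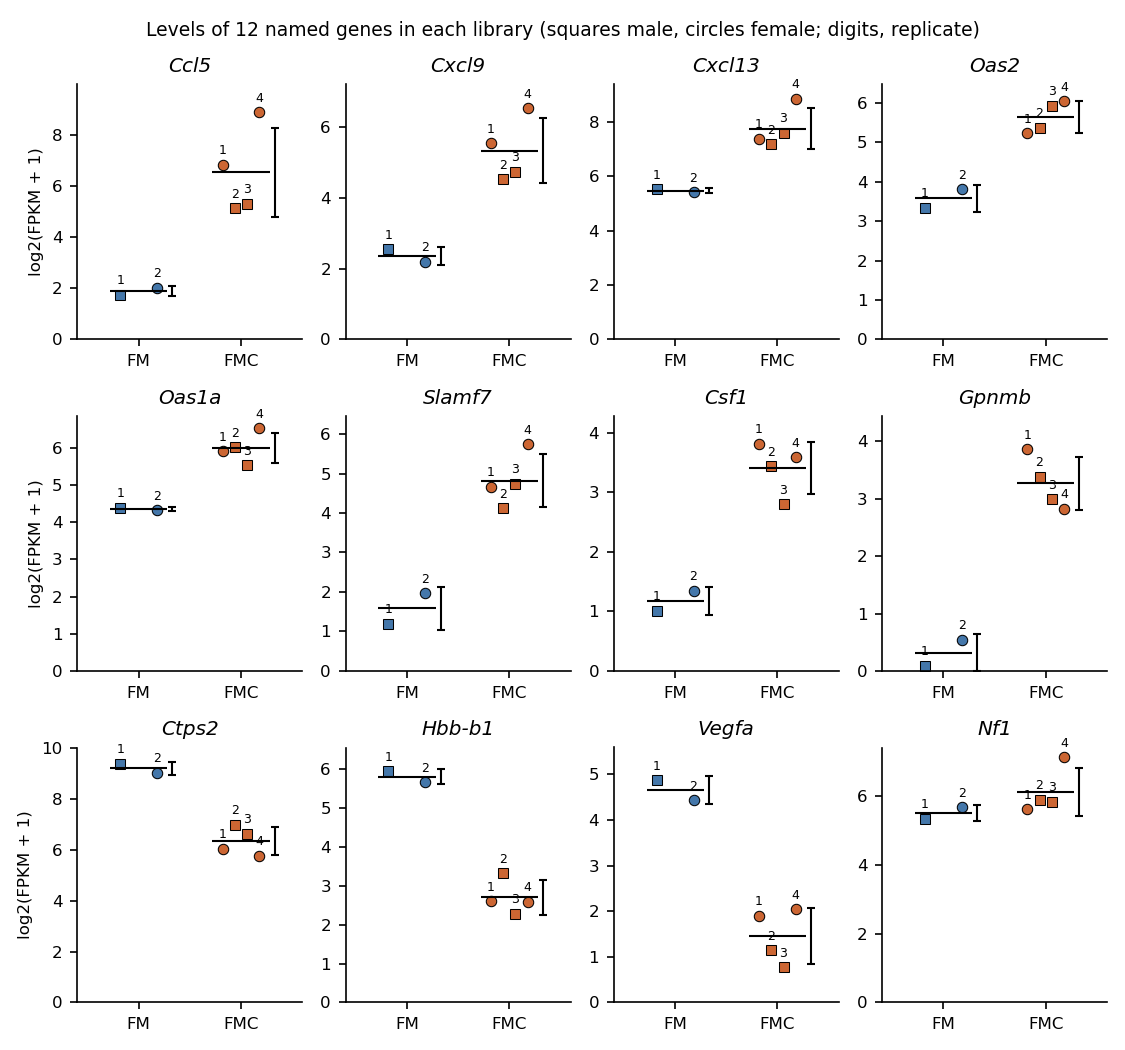
Levels of 12 named genes as log2(FPKM + 1), with 1 point per library (FM blue, n = 2; FMC orange, n = 4; squares male, circles labelled female), the group mean as a line and its SD as a bar. All 4 FMC points of Ccl5 lie above both FM points, those of Ctps2 lie below, and Nf1 overlaps; none of the 12 genes passed the test across all genes.

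Among the 12 genes lower in FMC by the same rule, Ctps2, which encodes a CTP synthase, was 595 ± 106 FPKM (SD, n = 2) in FM and 85.3 ± 32.6 FPKM (SD, n = 4) in FMC (log2 difference -2.86 ± 0.49 SE, adjusted p = 0.224). Hbb-b1, an adult beta globin gene, was 55.4 ± 7.4 and 5.76 ± 2.26 FPKM (log2 difference -3.11 ± 0.56 SE, adjusted p = 0.231). Mgp, an inhibitor of calcification made by vascular and connective tissue cells, was 101 ± 38 and 8.73 ± 5.57 FPKM. Scgb3a2, a secretoglobin, was at 22.6 and 68.5 FPKM in FM and at 0.664, 0, 0.254 and 2.82 FPKM in FMC 1 to FMC 4. Cmtm2a was at 55.9 and 47.9 FPKM in FM and at 0.0413, 0.0937, 0 and 3.08 FPKM in FMC. Among olfactory receptor genes, Olfr874 was at 27.5 and 35.8 FPKM in FM and at 0, 0.943, 0.0368 and 0.981 FPKM in FMC. Olfr1484 was at 61.3 and 54.7 FPKM in FM, at 4.81 FPKM in FMC 4 and listed at 0 in the other FMC libraries. Olfr282 was at 24.4 and 46.3 FPKM in FM and at 1.15, 0.296, 0 and 3.24 FPKM in FMC. The pseudogenes Defa-ps1 (21.0 and 55.0 FPKM in FM) and Olfr719-ps (24.6 and 258 FPKM) and the immunoglobulin heavy segment Ighv2-9-1 (69.1 and 9.30 FPKM) were listed at 0 in all FMC libraries. Vmn2r-ps125 (28.4 and 10.4 FPKM in FM) was listed at 0 in all but FMC 2, where it was 0.681 FPKM. Adjusted p ran from 0.113 to 0.312 over these 12 genes. Defa-ps1 passed in a fit without an intensity trend (adjusted p = 0.0431; 0.0431 to 0.935 over its alternatives). Globin, olfactory receptor and pseudogene values are uncertain where reads are shared between near-identical copies.

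Of 31 gene lists fixed before the data were examined, camera at its preset correlation called 7 higher and 3 lower in FMC. With an estimated correlation 0 of the 31 lists passed, and the smallest adjusted p was 0.396. At the preset correlation each of the other 14 splits of the libraries into 4 and 2 also gave between 2 and 11 lists. Interferon-stimulated genes rose as a list: 27 of 31 measured members were higher, with a median log2 difference of 0.62 (adjusted p = 9.5e-08; adjusted p = 0.605 with an estimated correlation). In 10 of the 31 all 4 FMC libraries lay above both FM libraries, and in 1 below both, where chance gives 6.67% of genes in each direction. Oas2, Oas1a (19.5 ± 0.6 FPKM in FM, n = 2; 64.8 ± 19.1 FPKM in FMC, n = 4; SD) and Zbp1, a sensor of Z-form nucleic acids (5.23 ± 2.84 and 26.4 ± 15.5 FPKM), had the smallest p of the list. No member passed over all genes, and 0 passed with p adjusted over the list alone. This list stayed past the threshold in all 17 other fits at the preset correlation, among them those with libraries of adjacent dates as a block (adjusted p = 0.000347) and without FMC 4 (adjusted p = 4.3e-05). Its mean was higher by 0.39 in FMC 2 than in FM 1 and by 0.69 in FMC 3 than in FM 2, the pairs with dates 1 day apart. The fit with the date block rests on these pairs, and FMC 3 and FM 2 differ in sex.

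Chemokines rose as a list, with 16 of 25 measured members higher and a median log2 difference of 0.31 (adjusted p = 0.00124; adjusted p = 0.605 with an estimated correlation). In 7 of the 25 all FMC libraries lay above both FM libraries and in 1 below, where chance gives 6.67% in each direction. Ccl5, Cxcl9 and Cxcl13 were the 3 members that passed with p adjusted over the list alone, and 0 passed over all genes. Its mean relative to the other genes was 0.83, and 0.62 without FM 1, where the list missed the threshold (adjusted p = 0.0714; 0.000246 to 0.0714 over its alternatives at the preset correlation). Its mean was higher by 0.88 in FMC 2 than in FM 1 but lower in FMC 3 than in FM 2, at -0.15.

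Genes described in disease-associated microglia rose as a list, with 13 of 21 members higher and a median of 0.24 (adjusted p = 0.00175; adjusted p = 0.605 with an estimated correlation). Gpnmb, Csf1 and Itgax had the smallest p. Csf1, a growth factor of macrophages, was 1.28 ± 0.37 FPKM (SD, n = 2) in FM and 9.98 ± 2.99 FPKM (SD, n = 4) in FMC, and the integrin gene Itgax 13.2 ± 8.3 and 43.5 ± 22.9 FPKM. In 4 of the 21 all FMC libraries lay above both FM libraries, where chance gives 6.67%. Over all genes 0 members passed, and 0 passed adjusted over the list alone. The list mean relative to the other genes was 0.75. The call was lost with adjacent dates as a block (mean 0.40, adjusted p = 0.270), without FM 1 (0.21, 0.716) and without FMC 4 (0.61, 0.0663), within a range of 6e-07 to 0.716 over its alternatives. The list mean was lower in FMC 3 than in FM 2 (-0.54) but higher in FMC 2 than in FM 1 (0.86).

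Both antigen presentation lists rose. Of the MHC class I list 12 of 13 members were higher (median 0.61, adjusted p = 0.00404), and of the MHC class II list 11 of 11 (median 0.64, adjusted p = 0.00633), both with an adjusted p of 0.605 with an estimated correlation. H2-Q4 was 21.2 ± 12.8 FPKM (SD, n = 2) in FM and 98.1 ± 63.6 FPKM (SD, n = 4) in FMC, H2-Q7 133 ± 128 and 403 ± 323 FPKM, and Tapbpl, which encodes a peptide editor, 3.94 ± 3.66 and 8.21 ± 2.95 FPKM. Cd74, the invariant chain of MHC class II, was 1817 ± 681 and 3977 ± 1074 FPKM, H2-Ab1 639 ± 282 and 1468 ± 703 FPKM, and H2-Eb1 553 ± 338 and 1513 ± 1293 FPKM. All FMC libraries lay above both FM libraries in 1 of 13 class I and 1 of 11 class II members, where chance gives 6.67%. No member of either list passed over all genes or adjusted over the list alone, and values of the H2 genes are uncertain where near-identical copies share reads. Relative to the other genes the list means were 0.90 and 0.82. Both calls were lost with adjacent dates as a block (means 0.52 and 0.36, adjusted p = 0.199 and 0.514), without FM 1 (means 0.43 and 0.36, adjusted p = 0.471 and 0.533) and without FMC 4 (means 0.64 and 0.56, adjusted p = 0.105 for both). Over the alternatives adjusted p ran from 7.8e-05 to 0.471 for class I and from 4.4e-05 to 0.533 for class II. In FMC 2 against FM 1 the means differed by 0.44 and 0.38, and in FMC 3 against FM 2 by 0.13 and -0.13.

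**Figure D2:**
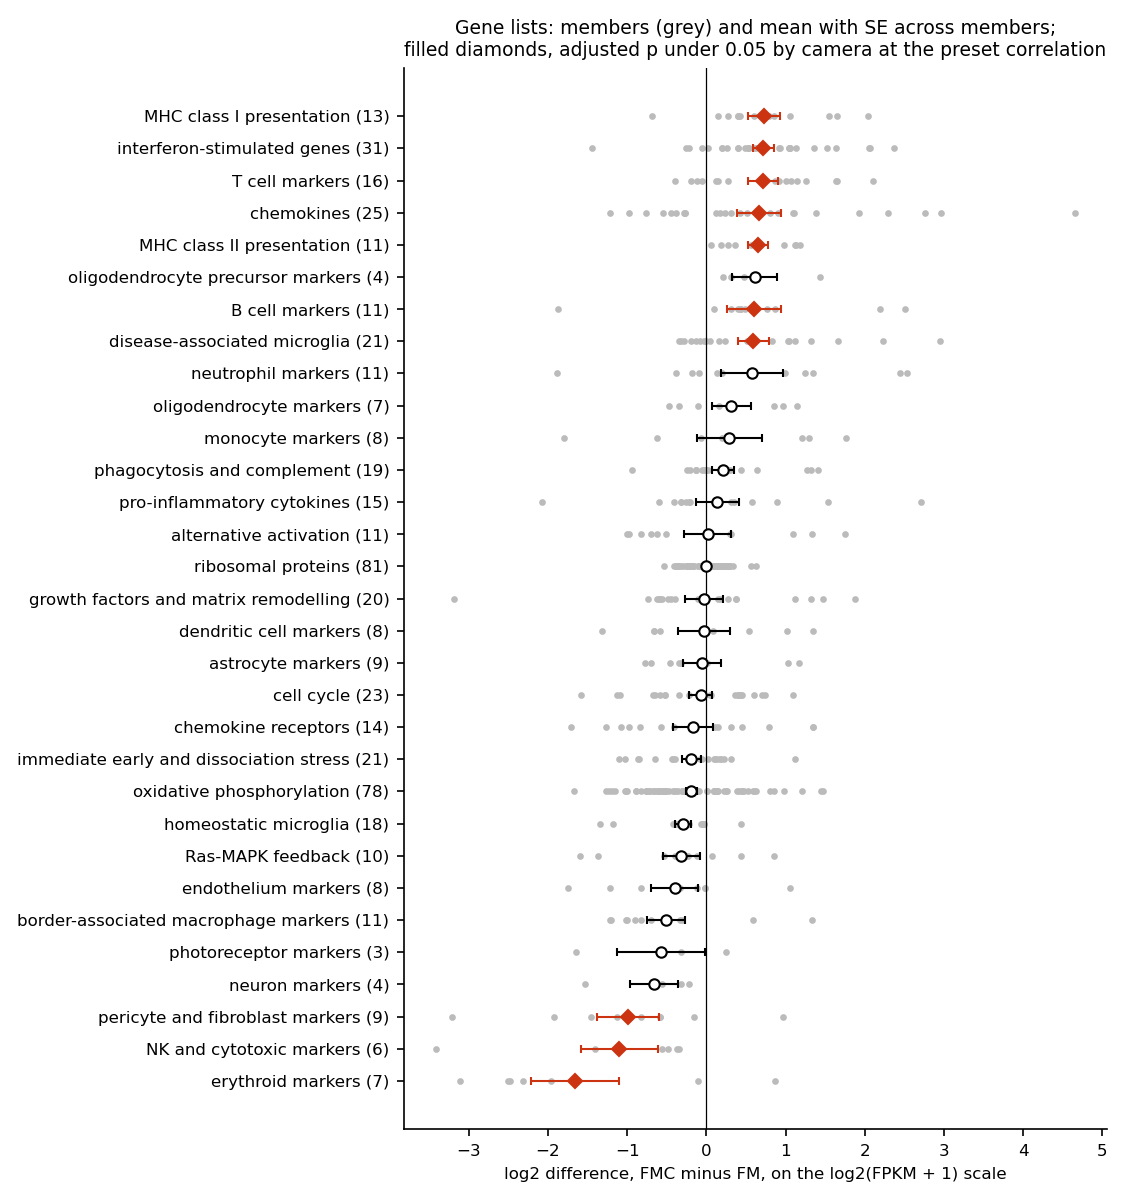
Log2 difference, FMC minus FM, of the measured members of each of the 31 lists (grey points; number of members in brackets), with the mean and its SE across members, which are not independent. The 10 filled diamonds are lists past the threshold by camera at the preset correlation, 7 with means above 0 and 3 with means below 0; with an estimated correlation 0 passed.

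Marker lists of other cell types, measured in the same sorted cells, also differed. T cell markers rose as a list (12 of 16 higher, median 0.89, adjusted p = 0.00519) and so did B cell markers (10 of 11 higher, median 0.43, adjusted p = 0.0248), each with an adjusted p of 0.605 with an estimated correlation. All FMC libraries lay above both FM libraries in 2 of 16 T cell and 2 of 11 B cell markers, where chance gives 6.67%. Relative to the other genes the list means were 0.88 and 0.77. Both calls were lost without FMC 1. Its T cell marker mean was 3.19 on the log2(FPKM + 1) scale, against 1.18 to 1.66 in the other 5 libraries, and without it the list means were 0.44 and 0.36 (adjusted p = 0.376 and 0.427). Without FM 2 they were 0.63 and 0.57 (adjusted p = 0.2002 for both), and without FM 1 B cell markers were at 0.96 (adjusted p = 0.0566). The ranges over the alternatives were 0.00106 to 0.376 for T and 0.00306 to 0.427 for B cell markers. Of the T cell genes, Lck was at 3.04 and 2.21 FPKM in FM and at 25.1, 11.8, 5.30 and 6.63 FPKM in FMC 1 to FMC 4. Cd247 was 1.03 ± 1.21 FPKM (SD, n = 2) in FM and 8.85 ± 5.80 FPKM (SD, n = 4) in FMC, and Cd5 0.0758 ± 0.0970 and 1.72 ± 1.58 FPKM. Of the B lineage genes, Cd79a was 1.17 ± 0.61 and 9.72 ± 5.76 FPKM and Igj, the joining chain of secreted antibodies, 1.06 ± 0.26 and 13.9 ± 11.8 FPKM, while Cd79b was at 61.9 ± 51.6 FPKM in FM and 20.7 ± 19.7 FPKM in FMC. With adjacent dates as a block the means were 0.50 and 0.61 and neither list passed (adjusted p = 0.201 for both). In FMC 2 against FM 1 the means differed by 0.09 for T and 0.11 for B cell markers, and in FMC 3 against FM 2 by 0.45 and 0.65.

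Erythroid markers fell as a list: 6 of 7 were lower, with a median of -2.32 (adjusted p = 0.000488; adjusted p = 0.396 with an estimated correlation). Here 5 of the 7 passed with p adjusted over the list alone and 0 over all genes, and in 5 of the 7 all FMC libraries lay below both FM libraries, where chance gives 6.67%. Hba-a1 was 30.6 ± 10.1 FPKM (SD, n = 2) in FM and 5.28 ± 3.03 FPKM (SD, n = 4) in FMC, and Hbb-b2 22.7 ± 5.2 and 3.83 ± 2.72 FPKM, beside Hbb-b1 above. Relative to the other genes the mean was -1.50, and -1.09 without FM 1 (adjusted p = 0.0816; 2.5e-06 to 0.0816 over the alternatives), and the mean was lower in both pairs of adjacent dates (-2.07 and -1.61). NK and cytotoxic markers fell as a list (6 of 6 lower, median -0.52, adjusted p = 0.0329; adjusted p = 0.605 with an estimated correlation), and 2 of the 6 passed with p adjusted over the list alone. In 2 of the 6 all FMC libraries lay below both FM libraries, and in 3 of the 9 pericyte and fibroblast markers, where chance gives 6.67%. Klrd1, an NK cell receptor subunit, was 60.1 ± 34.4 and 5.60 ± 5.19 FPKM, Gzmk 1.98 ± 0.75 and 0.103 ± 0.032 FPKM, and Klra7 was at 0.130 and 1.20 FPKM in FM and at 0, 1.10, 0.0497 and 0.0618 FPKM in FMC. Pericyte and fibroblast markers fell as a list (8 of 9 lower, median -0.83, adjusted p = 0.0337; adjusted p = 0.605 with an estimated correlation), and 1 of the 9 passed with p adjusted over the list alone. Tagln, an actin-binding protein of smooth muscle, was at 15.6 and 11.3 FPKM in FM and at 0.675, 1.79, 0.199 and 0 FPKM in FMC, Col1a1 8.65 ± 0.36 and 1.78 ± 1.43 FPKM, and Col3a1 3.61 ± 0.08 and 1.44 ± 1.40 FPKM. The NK call was lost in 8 of 16 alternatives (adjusted p 0.0086 to 0.500). The mean relative to the other genes, -0.93 without a block, was -1.005 with the block of adjacent dates (0.0602), -1.28 without FM 1 (0.127), -1.06 without FM 2 (0.274), -0.98 without FMC 2 (0.0857) and -0.64 without FMC 4 (0.230). The pericyte call, with a mean of -0.83, was lost in 7 of 16 (0.0012 to 0.534). The mean was -0.82 without FM 1 (0.127), -0.84 without FM 2 (0.117), -0.70 without FMC 2 (0.0857), -0.75 without FMC 3 (0.0805) and -0.60 without FMC 4 (0.170). Between libraries of adjacent dates the NK mean differed by -1.06 and -1.41 and the pericyte mean by -1.27 and -1.48. Of the 13 NK and cytotoxic genes listed, 6 were measured. Their mean log2(FPKM + 1) was 2.16 in FM 1 and 2.53 in FM 2, and 2.23, 1.10, 1.12 and 0.549 in FMC 1 to FMC 4. FMC 1 was thus not below FM 1.

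**Figure D3:**
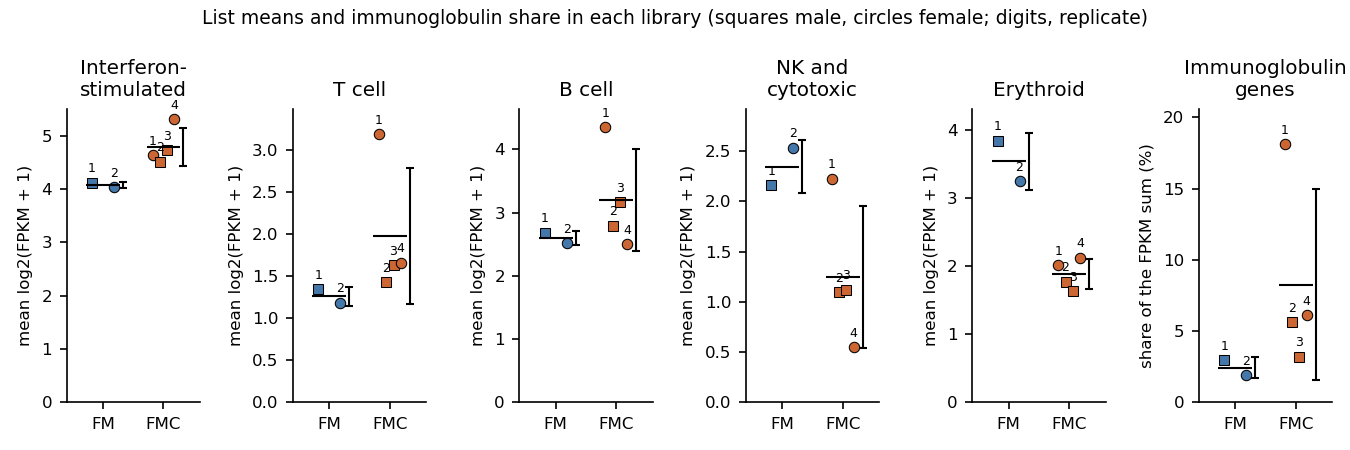
Mean log2(FPKM + 1) of the measured members of 5 lists, and the share of the FPKM sum from immunoglobulin genes in percent, with 1 point per library (FM blue, n = 2; FMC orange, n = 4), the group mean as a line and its SD as a bar. FMC 1 stands highest for T cell markers (3.19) and for the immunoglobulin share (18.1%), and FMC 4 for interferon-stimulated genes (5.31).

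The other 21 lists did not pass. Homeostatic microglia genes had a median of -0.24 (adjusted p = 0.366), with 17 of 18 members lower, among them the fructose transporter gene Slc2a5 at 299.9 ± 81.4 FPKM (SD, n = 2) in FM and 138 ± 56 FPKM (SD, n = 4) in FMC. After quantile normalization this list passed as lower (adjusted p = 0.0153; 0.0153 to 0.729 over its alternatives). Border-associated macrophage markers had a median of -0.82 (adjusted p = 0.0727), with Pf4 at 168 ± 56 and 72.6 ± 26.5 FPKM. Growth factors and matrix remodelling genes had an adjusted p of 0.831, and Vegfa, at 28.2 and 20.6 FPKM in FM and 2.74, 1.21, 0.701 and 3.13 FPKM in FMC, passed with p adjusted over that list alone (0.0409) but not over all genes (adjusted p = 0.465). Adjusted p was 0.153 for neutrophil markers (Ly6g 3.33 ± 4.13 and 17.6 ± 6.6 FPKM), 0.227 for monocyte markers (Itgal 6.16 ± 0.63 and 27.0 ± 14.5 FPKM), 0.199 for phagocytosis and complement (C3 25.4 ± 20.3 and 63.3 ± 27.8 FPKM), 0.422 for pro-inflammatory cytokines (Il1rn 0.83 ± 0.30 and 13.1 ± 8.8 FPKM), 0.946 for alternative activation (Cd274 2.16 ± 0.24 and 10.7 ± 4.9 FPKM) and 0.831 for chemokine receptors (Ccr10 at 1.82 and 3.58 FPKM in FM and 0, 0.113, 0.0389 and 0.244 FPKM in FMC). Dendritic cell markers had an adjusted p of 0.946 (Cd209a 2.98 ± 2.21 and 0.492 ± 0.307 FPKM). It was 0.681 for Ras-MAPK feedback genes (Spry2 at 3.97 and 1.04 FPKM in FM and 0, 0.619, 0.0880 and 0.312 FPKM in FMC), 0.831 for the cell cycle (Top2a 38.1 ± 5.2 and 17.8 ± 6.7 FPKM), 0.831 for immediate early and dissociation stress genes (Jun 416 ± 136 and 231 ± 70 FPKM), 0.374 for ribosomal proteins (Rpl22l1 67.2 ± 20.0 and 106 ± 48 FPKM) and 0.831 for oxidative phosphorylation (Ndufa6 18.4 ± 7.4 and 52.8 ± 18.02 FPKM). Among markers of neural and vascular cells, adjusted p was 0.374 for oligodendrocytes (Mbp 2.47 ± 2.01 and 7.81 ± 6.98 FPKM), 0.238 for their precursors (Olig2 at 0.382 and 0.151 FPKM in FM and 0.354, 9.36, 0 and 8.63 FPKM in FMC), 0.856 for astrocytes (Fgfr3 0.243 ± 0.090 and 1.94 ± 1.88 FPKM), 0.396 for neurons (Syp 9.62 ± 9.10 and 3.47 ± 4.74 FPKM), 0.366 for photoreceptors (Prph2 at 2.34 and 3.24 FPKM in FM and 0.134, 0, 0 and 0.830 FPKM in FMC) and 0.681 for endothelium (Ly6c1 9.38 ± 1.12 and 3.77 ± 5.60 FPKM). Prph2 passed with p adjusted over its list alone (0.0382). Of these examples 0 passed over all genes by limma. Omitting 1 library brought some of these lists past the threshold. Without FM 1 these were monocyte (adjusted p = 0.0220) and neutrophil markers (3.7e-05), and without FM 2 phagocytosis and complement (0.00546) and ribosomal proteins (1.1e-07). Ribosomal proteins were called in opposite directions: higher in FMC without FM 2, and lower without FM 1 (mean relative to the other genes -0.47, adjusted p = 0.00214). Without FMC 1 border-associated macrophage markers passed (0.0241), and ribosomal proteins passed as higher without FMC 2 (0.0337) and without FMC 3 (0.00591). Median, mean and test differed in sign for growth factors, pro-inflammatory cytokines, alternative activation, the cell cycle, phagocytosis and complement, ribosomal proteins, astrocyte and dendritic cell markers, whose members moved both ways.

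The comparison of 3 male with 3 female libraries, with genotype in the model, gave 0 genes past the threshold by limma, with 1354 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.0901. Eif2s3y, a translation initiation factor gene on chromosome Y from 346986 to 365290, was at 114, 81.9 and 57.8 FPKM in the males FM 1, FMC 2 and FMC 3, listed at 0 in FM 2 and at 1.39 FPKM in FMC 4 (male minus female log2 5.24 ± 0.68 SE, adjusted p = 0.169). The library labelled female as FMC 1 carried transcripts of both kinds. It had the highest Xist, the RNA of the inactive X chromosome, at 16.3 FPKM, and also Uty at 16.3, Ddx3y at 6.18, Eif2s3y at 3.37 and Kdm5d at 0.926 FPKM. The females FM 2 and FMC 4 had 0.819 and 1.22 FPKM of Xist and at most 1.39 FPKM of these Y-linked genes, and the 3 males had 0.0688 to 0.0742 FPKM of Xist and at least 24.0 FPKM of Uty, 5.82 of Ddx3y and 11.2 of Kdm5d. Without FMC 1, 4 genes passed, all unnamed gene models higher in males (AC125010.1, AC102463.2, AC157101.1 and Gm17386, named after their values were seen). The split of FM 2 and FMC 4 against the rest, which puts FMC 1 with the males, also called these 4 genes. Their differences were nearly the same, at 13.2 (log2) for AC125010.1 in both fits. In these genes FMC 1, labelled female, thus went with the males. Without FM 1, and also without FM 2, the genes past the threshold were Gm10281 and AC122209.1. Without FMC 2 they were AC131591.1 and AC163028.1, and without FMC 4 it was AC142100.1, all likewise named after their values were seen.

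**Figure D4:**
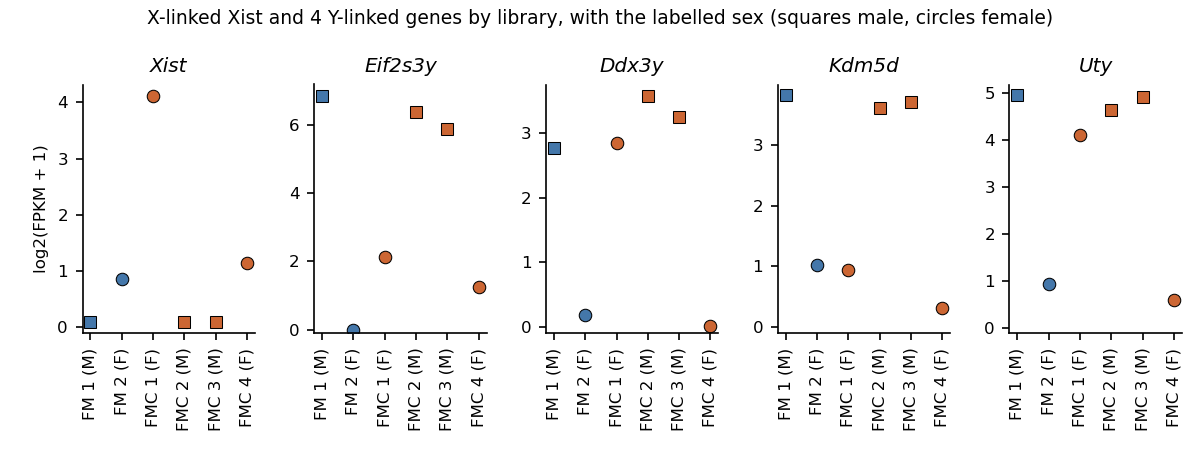
Xist and 4 genes of chromosome Y as log2(FPKM + 1), 1 point per library (FM blue, FMC orange; squares labelled male, circles labelled female). FMC 1, labelled female, has the highest Xist (16.3 FPKM) and also Uty at 16.3 FPKM.

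Whether the genotype difference depends on sex was asked with an interaction term, which leaves 2 residual degrees of freedom because each sex of FM is 1 library. It gave 0 genes past the threshold by limma, with 686 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.999. The library labelled female as FMC 1 enters this comparison, and without it the count was also 0.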

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

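No test in this part was chosen after its result was seen, and no explanation was tested for these values. In the FMC group of 4 libraries, 80 checks of named genes and library measures picked 5 values that stand far from the other 3; chance picks about 1 in 20. These were Cmtm2a at 3.08 FPKM and Olfr1484 at 4.81 FPKM in FMC 4, Vmn2r-ps125 at 0.681 FPKM and Klra7 at 1.10 FPKM in FMC 2, and Tapbpl at 3.87 FPKM in FMC 1, where the other FMC libraries had 9.12 to 10.4 FPKM.

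In 3 of 76 named genes both FMC libraries of 1 sex lay above the FM library of that sex and both of the other sex below it. Genes whose groups do not overlap, many of them named for that reason, cannot meet this rule. The 3 of 76 is therefore not a rate of sex dependence. For Gfap, the male difference (FMC minus FM) exceeded the female one by 1.76 (log2), and this difference was not tested because the gene lay under the filter of the limma fit. For Xist it was -1.78 and for Eif2s3y -2.42, both with an adjusted p of 0.999 for the interaction by limma. The library labelled female as FMC 1 holds Y-linked transcripts and the highest Xist, and both of these values include it.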

How the results depend on the processing

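Fry was chosen after seeing the data. Ccl5 kept its direction and missed the threshold in all 17 alternatives (log2 difference 3.34 to 5.13, adjusted p 0.217 to 0.996). No named gene passed except Igkv17-127 without FMC 4 and Defa-ps1 without an intensity trend. The count of genes higher in FMC, 0, was 1 with a pseudocount of 0.1, 2 with the date block, and 0 to 4 when 1 library was left out. The count lower, 5, was 0 with a pseudocount of 0.1, without a filter, with a mean of at least 5 FPKM, without small and unnamed RNAs, and with sex as a covariate, 1 with the date block, 10 without an intensity trend, and 0 to 4 with 1 library left out. Omitting small RNAs, FM 1 or FM 2 removes the called genes themselves from the fit, and the cause of the other shifts was not tested. The count of lists, 10, was 0 with an estimated correlation, 2 by fry, 6 with the date block (2 of them, oxidative phosphorylation and ribosomal proteins, not among the 10), and 5 to 10 with 1 library left out. Fry called erythroid and photoreceptor markers (adjusted p = 0.0319 for both). The sex count, 0, was 0 to 4 with 1 library left out, and the interaction count stayed 0 in 12 alternatives and could not be fitted without FM 1 or FM 2.

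Same-numbered libraries share only a number: FM 1 and FMC 1, and FM 2 and FMC 2, differ in sex, and their deviations from the group means correlated at 0.03 and -0.06 across genes. The pairs with adjacent dates, FM 1 with FMC 2 and FM 2 with FMC 3, had 0.06 and -0.07. FM 2 and FMC 3 also differ in sex. FMC 1 and FMC 4 are each alone in their date block, so the genotype difference with the date block rests on these pairs. With 2 FM libraries the deviations of FM 1 and FM 2 are equal and opposite. Each value for FM 2 is therefore that for FM 1 with the sign turned, and these values cannot decide for or against either pairing. With the replicate block the counts were 0 higher and 0 lower, 8 lists passed, and Ccl5 was at 4.10. Among the 8 were monocyte and neutrophil markers, which the main fit did not call. The MHC class I (mean 0.45) and class II lists (0.47), NK (-0.49) and pericyte markers (-0.36) were lost under the replicate block.

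Of the lists past the threshold, only interferon-stimulated genes passed in every alternative at the preset correlation. Lists not called passed in 20 cases, 6 of them for border-associated macrophage markers and 2 with the sign turned, both for ribosomal proteins (date block, adjusted p = 0.000347; without FM 1, 0.00214). Means relative to the other genes (log2) turned sign in 11 lists that were not called, and the cause was not tested. With a pseudocount of 0.1 they were -0.00235 for astrocyte markers, 0.000899 for homeostatic microglia, 0.0744 for immediate early genes and 0.0780 for oxidative phosphorylation. Without a filter astrocyte markers were at -0.0518. With a mean of at least 5 FPKM, Ras-MAPK feedback was at 0.0748 and the cell cycle at -0.31. Quantile normalization gave 0.00629 for chemokine receptors and -0.13 for ribosomal proteins, array weights 0.0302 for immediate early genes, and the replicate block 0.0340 for chemokine receptors. The date block gave 0.14 for chemokine receptors, 0.56 for immediate early genes and -0.48 for ribosomal proteins, and, among genes, 1.24 for Kdm5d and -0.38 for Xist.

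With 1 library left out the ranges that cross 0 were -0.24 to 0.0322 for Ras-MAPK feedback, -0.0333 to 0.39 for alternative activation, -0.19 to 0.41 for astrocyte markers, -0.30 to 0.45 for the cell cycle, -0.11 to 0.22 for chemokine receptors, -0.79 to 0.0707 for endothelium, -0.38 to 0.11 for homeostatic microglia, -0.24 to 0.20 for immediate early genes, -0.61 to 2.09 for neutrophil markers, -0.25 to 0.14 for oxidative phosphorylation and -0.47 to 0.80 for ribosomal proteins. Among sex-linked genes they were -0.35 to 2.25 for Ddx3y, -2.94 to 3.91 for Eif2s3y, -1.67 to 1.13 for Kdm5d and -1.39 to 2.62 for Uty.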

Other observations

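All tests of explanations in this part were chosen after the results were seen. Immunoglobulin genes, counted after their values were seen, took 2.95% of the FPKM sum in FM 1 and 1.91% in FM 2, against 18.1% in FMC 1, 5.64% in FMC 2, 3.21% in FMC 3 and 6.11% in FMC 4 (259 genes). Igkc, the kappa constant region, was at 3363 and 2585 FPKM in FM and at 49907, 10620, 6236 and 16959 FPKM in FMC 1 to FMC 4.

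Other chemokines of the interferon response had values in the direction of Ccl5. Cxcl11 was at 0.800 and 1.48 FPKM in FM and at 13.5, 5.28, 9.51 and 43.3 FPKM in FMC (limma adjusted p = 0.676), and Cxcl10 at 96.1 and 66.5 FPKM in FM and 141, 202, 128 and 527 FPKM in FMC (adjusted p = 0.956). Isg15, itself an interferon-stimulated gene, did not follow, with 12.3 and 19.1 FPKM in FM and 7.11, 12.7, 9.81 and 28.02 FPKM in FMC. These 3 genes were chosen after their values were seen.

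Ccl5 was higher in all 4 FMC libraries. T or NK cells, which also make Ccl5, are a candidate source, although a flow sort for microglia is meant to remove them. The 22 measured T and NK markers had a median log2 difference of 0.13 (SD across markers 1.20, highest 2.10), against 4.66 ± 0.98 (SE) for Ccl5. The T cell markers alone had a median of 0.89. The NK markers had -0.52, with 6 of 6 lower, which gives no sign of more NK cells. The log2(FPKM + 1) scale compresses markers that are low in FM. Cd5, at 0.0758 FPKM in FM and 1.72 FPKM in FMC, differed by only 1.14, and Cd247, at 1.03 and 8.85 FPKM, by 2.10. The comparison therefore cannot decide whether more T cells are the source. FMC 4 alone does not account for the difference, since without it Ccl5 differed by 3.87 ± 0.68 (SE). More T cells, a change in the state of T cells, or one in microglia of FMC mice as the study design poses it, stay open. Ccl5 did not pass the test across all genes.

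Interferon-stimulated genes were higher in FMC as a list, with p = 3.1e-09 by camera at the preset correlation and p = 0.0768 (adjusted p = 0.605) with an estimated correlation. The values of camera that follow are at the preset correlation. In 1 of the 15 splits of the libraries into 4 and 2, the real one, p was that small; the smallest of the other 14 was 1.5e-07, for FMC 3 and FMC 4 against the rest, and 15 splits are too few for a share under 0.05. FMC 4 alone does not account for the size of the difference. Without it the list stood 0.78 above the other genes (log2, adjusted p = 4.3e-05), against 0.89 with it. The list was not tested with an estimated correlation without FMC 4, so this p has the same limit as those above. The genotype, and a spread of interferon genes between libraries that is not due to genotype, both stay open.

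The 5 genes lower in FMC may reflect chance detection of small RNAs, that is, detection in any pair of libraries by chance. The FM pair had 45 genes at 1 FPKM or more in both of its libraries and at 0 in the other 4, and 3 of the 15 pairs, the FM pair included, had as many (15 to 49 in the other pairs, median 28). Of the other 14 pairs only 2 reach that number. In genes called by limma, 5 of the 15 splits, the real one included, gave 5 or more. The split of FM 1 and FMC 2 against the rest also gave 5, all lower in the 4 and all at 0 on 1 side. These counts do not decide between chance detection and a loss of these RNAs in FMC, and both stay open.

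Across the 15 splits, the real one gave 5 genes and 10 lists, and the highest of the others gave 29 genes (FM 2 and FMC 4 against the rest) and 11 lists. Of the 15 splits, 5, the real one included, gave 5 genes or more. Every split gave at least 2 lists, and 3 of the 15, the real one included, gave 10 or more. The split of FMC 1 and FMC 3 against the rest gave 21 genes. At 0 in all libraries of 1 side were 14 of the 29 genes and 18 of the 21. FM 2 and FMC 4 are both labelled female, have low Y-linked transcripts, and had the highest correlation of all pairs (0.758 across genes). FMC 3 and FMC 4 were close to that at 0.757, and their split gave 1 gene. The pair of FM 2 and FMC 4 had 49 genes at 1 FPKM or more in both and at 0 in the other 4 libraries. FMC 1 and FMC 3 had 29, where the median of the pairs other than FM was 28. Why these splits gave several times the real count was not tested. For sex, the real split of 3 against 3 gave 0 genes and the highest of the other 9 gave 6. With 0 genes in the real split, 10 of 10 splits give at least as many by construction, so this count decides nothing.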
